A study of Populus ussuriensis with 12 samples.

How the data were processed

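Messenger RNA was measured in leaves of Populus ussuriensis in a design of genotype (wild type or a line overexpressing Pu-miR172d) and watering (watered or 4 days without water), with 3 libraries in each of the 4 groups. Per the labels' protocols, plants were kept in vitro for 4 weeks, moved to soil in 300 ml pots and grown at 25 °C with 16 h of light and 8 h of dark, and leaves 7 and 8 were taken at an age of 70 days. RNA was extracted with Trizol, libraries were made from 2 µg of RNA with a NEBNext Ultra kit and sequenced on an Illumina HiSeq as paired reads of 150 bp, to about 4 Gb per library, per the labels' protocols. That kit does not mark strand, so reads of overlapping antisense genes cannot be told apart.

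The authors deposited gene expression values in FPKM (fragments scaled to the length of the gene and the total of the library), with gene positions and functional descriptions in the same table. The submitters' processing notes name HISAT2 2.1.0 and Bowtie2 2.2.3, without the role of each. The genome build and the counting tool are not given in the sources used here. The annotated table held 35747 genes, of which 26925 had a UniProt description and 21804 a biological process term. A second deposited table of FPKM values held 16749 genes, of which 16748 were identical to the first in every library, and was not used further. No reference genome was used here, and positions are those of the authors' table.

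FPKM does not state depth, but its low values are steps of what 1 fragment is worth. For 35675 genes (99.8%) the values of all libraries came out as whole fragments within a tolerance of 0.02, and the library totals from this step ranged from 9682111 to 12131416 fragments. For 6486 genes the span of the gene gave the same totals. These recovered fragments served for depth and for an alternative fit. FPKM stays the unit of every reported value. At this depth 1 FPKM rests on few fragments for a short gene, so that weak genes carry larger counting error.

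Samples were grouped by the labels, which give genotype, watering and replicate number. Replicates of a group were compared first: no library held the same values as another, and pairs within a group differed by a chi-square of 11.2 to 67.6 per gene, where 1 is sampling noise, except OE drought replicates 4 and 6, which differed by 3.75. None was thus a repeat of the same library within counting noise, and each counted as a replicate, though repeat libraries of a plant or pool are not ruled out. Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested (25373 genes). log2(FPKM + 1) values were fitted with limma 3.58.1 in R 4.3.3 to the 4 group means, with 8 residual degrees of freedom and an empirical Bayes variance that follows expression level (median prior degrees of freedom 3.79). All groups share this estimate of the spread. The contrasts were drought against watered in each genotype, OE against WT in each watering, and the interaction. p-values were adjusted by Benjamini-Hochberg over all tested genes of a contrast, with a threshold of 0.05. The series states a fold change of 1 or more with a false discovery rate under 0.05. A linear fold of 1 excludes nothing, so a log2 fold change of at least 1 was an alternative.

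Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 110 tests of the 22 lists with tested genes in 5 contrasts. Of these, 33 passed. With a correlation estimated from the data 0 of the 110 passed (adjusted p = 0.954 with an estimated correlation for each of the 33). limma's fry asks whether the genes of a list move on balance in a direction (38 lists) or change at all (84 lists), without comparing them with other genes. The 23 lists covered miR172 targets, stomatal lineage, guard cell, ABA synthesis and breakdown, ABA signalling, dehydration response, photosystems and antenna, Calvin cycle, cell division, heat shock and chaperones, antioxidant enzymes, phenylpropanoid and flavonoid, wax and cutin, aquaporins, wall expansion, xylem secondary wall, phloem, epidermis and trichome, meristem (1 gene, not tested since it lay below the filter), flowering and age, senescence and chlorophyll breakdown, jasmonate and circadian clock. Their members were found by patterns in the gene descriptions, since the files do not pair genes with Arabidopsis loci. The groups, tests, list themes, named-gene rule and most alternatives were set first. Exclusions from the patterns (such as chaperones of a listed enzyme) and whole-word matching of short names were set from the descriptions afterwards, before any test, and the lists without them are an alternative. Functional terms of 5 to 500 genes were tested with a one-sided Fisher's exact test among tested genes that carry a term.

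Genes are named by this rule, per contrast: every miR172 target, GTL1 and SDD1 homologue; from every other list up to 4 members past the threshold with the largest absolute change, or the member with the smallest p as a value; and up to 10 higher and 10 lower genes with the largest absolute change among those past the threshold with a mean of at least 5 FPKM in a compared group, no overlap between replicates (not asked of the interaction) and an informative description. Fewer may be named, in order of size. Which of a list's 4 members are named was chosen after their values were seen, mostly as those whose calls hold across alternatives. No fold is given against a group whose libraries are all listed at 0.

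The fit was tested on simulated fragments with known changes. At a true fold of 2, of the simulated changed genes, 65.5% were recovered in WT drought (24408 genes in the step), 72.1% in OE drought (24439), 80.6% in watered OE against WT (24418), 83.6% in drought OE against WT (24414) and 18.8% in the interaction (24374), and at a fold of 4 these were 98.4%, 100%, 98.5%, 96.9% and 90.3%. Between 3 and 15 unchanged genes were called per contrast. The simulation gave all genes the same dispersion (0.0215) and set no library apart from its group, so these shares may overstate recovery in the real libraries. In a simulated list test with camera the shifted list passed and 0 of 40 unchanged lists did. Genes were drawn independently there, so it does not test the preset correlation between genes.

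Alternatives set before the data were examined were a pseudocount of 0.1, no filter and a filter on mean FPKM, median-of-ratios scaling, a fit of only the groups compared, a log2 fold change of at least 1, the replicate number as a block, the estimated correlation and fry for lists, and leaving out each replicate in turn. Tests made for raw counts were meant for that case only and were not run on FPKM. Chosen after seeing the data were voom on the recovered fragments (25301 genes), a fit without the 3 libraries apart from their groups, scaling by the FPKM outside the 100 most abundant genes, and the list patterns before exclusions. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 prepared the tables.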

Results

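Leaf RNA of the poplar Populus ussuriensis was sequenced in 12 libraries, 3 in each of 4 groups. The plants were wild type (WT) or overexpressed the microRNA Pu-miR172d (OE), and plants of each genotype were either watered or kept without water for 4 days. The labels name stomatal development and drought as the subject, and miR172 is known to repress transcription factors of the APETALA 2 (AP2) family. Leaves 7 and 8 from the shoot tip were taken from plants grown in soil. Replicates carry the numbers of the labels, 1 to 3 in the watered and 4 to 6 in the drought groups. The labels do not say whether replicates were separate plants, so p-values measure only the spread between these samples, which may be technical.

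The libraries held 9682111 to 12131416 fragments, as recovered from the steps of the FPKM values. They held 9682111 to 10557749 fragments in WT watered, 11645616 to 12028945 in WT drought, 9793188 to 10710916 in OE watered and 11602784 to 12131416 in OE drought samples (n = 3 each). Between 29750 and 30686 genes lay above 0 FPKM. The 100 most abundant genes took 24.9 to 29.3% of the summed FPKM in watered libraries and 16.7 to 22.5% in drought libraries. Levels are given as mean FPKM ± SD over 3 libraries. Changes are log2 fold changes ± SE on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes. A gene is said to rise or fall where limma gave a Benjamini-Hochberg adjusted p under 0.05.

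Watering separated the libraries most. On the first principal component, with 77.3% of the variance, watered libraries lay between -130.4 and -79.6, WT drought libraries between 71.9 and 81.9 and OE drought libraries between 132 and 173. Within their own groups, OE watered replicate 2, WT drought replicate 6 and OE drought replicate 5 had the lowest mean correlations with the other libraries, of 0.949, 0.926 and 0.962. Those of WT drought replicates 4 and 5 (0.947 and 0.950) and OE watered replicate 3 (0.952) were lower than the last of these.

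**Figure D1:**
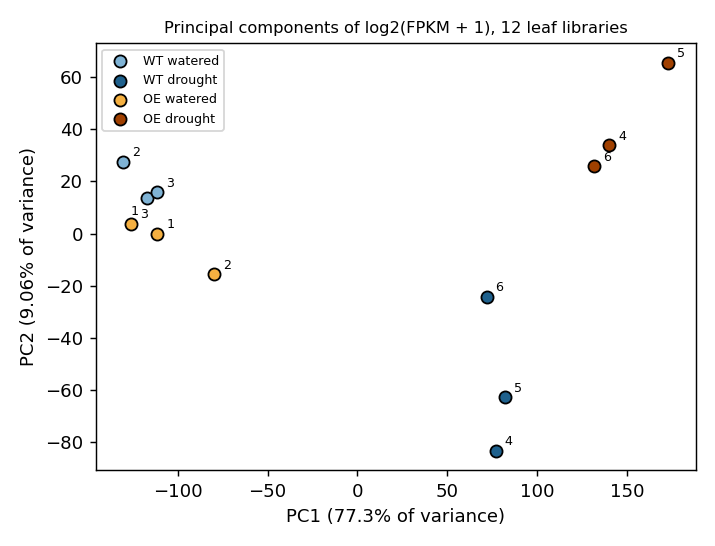
Scores of the 12 libraries on the first (77.3% of the variance, horizontal axis) and second (9.06%, vertical axis) principal components of log2(FPKM + 1), each point a library coloured by its group. Drought libraries lie at 71.9 or more on the first component, watered libraries at -79.6 or less.

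The overexpressed microRNA was not analysed here. Of its known targets, the files describe 6 genes as AP2, and none of the 6 passed the limma threshold as lower in the libraries labelled OE, in watered leaves or in drought, so the targets gave no check of the genotype labels. OE and WT are used as the labels give them. In watered leaves 0 of the 6 differed between genotypes with limma, over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, and 0 passed with voom on recovered fragments. The differences, OE minus WT, ran from -0.19 ± 0.17 (Potri.005G140700, adjusted p = 0.830, 95% interval -0.56 to 0.19) to 0.33 ± 0.22 (Potri.007G046200, adjusted p = 0.722, 95% interval -0.14 to 0.80). In drought 3 of the 6 were higher in OE leaves, also 3 when adjusted over the list alone. Potri.005G140700 (chromosome 5, 11805773 to 11809765, plus strand) stood at 4.32 ± 0.874 FPKM in WT and 9.03 ± 0.762 FPKM in OE drought leaves (0.93 ± 0.17, adjusted p = 0.00339), and Potri.010G216200 (chromosome 10, 20332984 to 20337268, plus strand) at 3.61 ± 0.639 and 9.98 ± 3.50 FPKM (1.21 ± 0.29, adjusted p = 0.0109). The third gene, Potri.016G084500 (chromosome 16, 6598225 to 6602171, plus strand), differed by 0.78 ± 0.24 (adjusted p = 0.0312). Its call ended without WT drought replicate 4 (adjusted p = 0.0862) and without OE drought replicate 4 (0.0828), 5 (0.0580) or 6 (0.0702), and was 0.126 with only the drought groups fitted, within a range of 0.0113 to 0.126 over all alternatives. As a list the 6 genes were higher in OE drought leaves (camera adjusted p = 0.0152), with adjusted p = 0.954 with an estimated correlation. With directional fry the list did not pass (adjusted p = 0.0845). Without OE drought replicate 6 the camera adjusted p was 0.0647, within 0.00149 to 0.0647 over the libraries left out. The genome build of the coordinates is not given in the sources used here.

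Drought itself lowered the AP2 gene Potri.005G140700 in WT leaves, from 15.0 ± 0.438 to 4.32 ± 0.874 FPKM (-1.60 ± 0.17, adjusted p = 1.73e-05). In OE leaves it fell by less, from 13.2 ± 2.62 to 9.03 ± 0.762 FPKM (-0.49 ± 0.17, adjusted p = 0.0269), and the difference between these responses was 1.11 ± 0.24 (adjusted p = 0.0153). The OE call ended without OE watered replicate 2 (adjusted p = 0.110), OE drought replicate 4 (0.0567) or OE drought replicate 5 (0.0749), and with median-of-ratios scaling (0.0647), within a range of 0.0169 to 0.112. Among the 6 genes 0 rose and 2 fell in WT drought (adjusted over the list alone, 0 and 2), and 1 rose and 2 fell in OE drought (adjusted over the list alone, 0 and 2). The other calls did not hold without single libraries. Potri.016G084500 fell in WT by -0.67 ± 0.24 (adjusted p = 0.0323; 0.0634, 0.0607 and 0.0926 without WT watered replicates 1, 2 and 3, 0.110 without WT drought replicate 4, 0.0927 with only the WT groups fitted, range 0.00579 to 0.110). Potri.007G046200 fell in OE (-0.71 ± 0.22, adjusted p = 0.0128; 0.0549 without OE watered replicate 2 and 0.0525 without OE drought replicate 5, range 0.00839 to 0.0654). Potri.010G216200 rose in OE (0.72 ± 0.29, adjusted p = 0.0462). That p was 0.0563 and 0.0542 without WT watered replicates 1 and 3, 0.0517 and 0.0566 without WT drought replicates 4 and 5, 0.170 and 0.116 without OE watered replicates 1 and 3, and 0.112 and 0.178 without OE drought replicates 4 and 6, and it also passed 0.05 with the other pseudocount, without the filter, with only the OE groups fitted and with scaling outside the 100 most abundant genes, in a range of 0.00203 to 0.178.

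**Figure D2:**
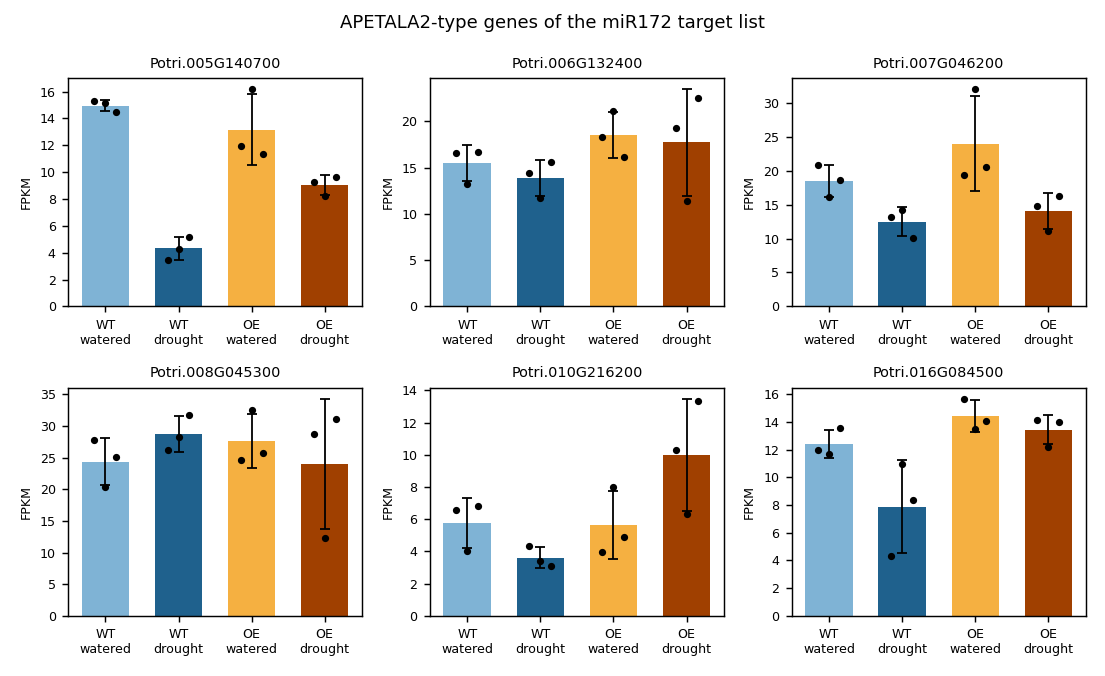
FPKM (vertical axis) of the 6 genes described as AP2 in the 4 groups (horizontal axis), with bars for group means, error bars for the SD and points for the 3 libraries. Potri.005G140700 stands at 4.32 FPKM in WT drought and 9.03 FPKM in OE drought leaves, while 0 of the 6 genes pass the test between watered genotypes.

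The trihelix factor GTL1 and the protease SDD1 (described as SBT1.2) are known to act together on stomatal density, GTL1 by repressing SDD1. Both GTL1 homologues fell in drought in both genotypes. Potri.001G454500 fell from 25.5 ± 3.17 to 8.20 ± 1.22 FPKM in WT (-1.53 ± 0.27, adjusted p = 6.43e-04) and from 27.3 ± 4.80 to 5.48 ± 2.48 FPKM in OE leaves (-2.20 ± 0.27, adjusted p = 2.67e-05). For Potri.011G147400 the changes were -0.98 ± 0.34 in WT (adjusted p = 0.0268) and -1.66 ± 0.34 in OE (adjusted p = 0.00109). The WT call ended without WT watered replicate 1, 2 or 3 (0.0746, 0.0586 and 0.0515) and without WT drought replicate 4 or 5 (0.0685 and 0.0910), in a range of 3.54e-04 to 0.0910. Of the 5 SDD1 homologues 4 were too weakly expressed to test. Potri.002G256300 fell from 1.88 ± 0.862 to 0.551 ± 0.407 FPKM in WT (-0.88 ± 0.26, adjusted p = 0.0118, and 0.0543 without WT watered replicate 1, range 0.00446 to 0.0543) and from 2.05 ± 0.668 to 0.265 ± 0.0742 FPKM in OE (-1.25 ± 0.26, adjusted p = 0.00118). Between genotypes the 3 genes did not pass the test, with differences of 0.09 ± 0.27, 0.25 ± 0.34 and 0.10 ± 0.26 in watered leaves (adjusted p = 0.965, 0.907 and 0.957) and of -0.58 ± 0.27, -0.43 ± 0.34 and -0.27 ± 0.26 in drought (adjusted p = 0.123, 0.353 and 0.456).

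The first comparison asks how WT leaves responded to 4 days without water. The sugar transporter SWEET15 (Potri.001G060900) rose from 0.527 ± 0.509 to 927 ± 422 FPKM (9.17 ± 0.49, adjusted p = 1.20e-07), followed by CEN-like protein 1 (Potri.015G141300, 8.68 ± 0.49, adjusted p = 1.64e-07) and a pair of 18 kDa seed maturation proteins (Potri.T111300, 8.43 ± 0.35, adjusted p = 2.63e-08; Potri.016G046400, 8.35 ± 0.31, adjusted p = 2.11e-08). Galactinol synthase 1 (Potri.008G101000), which opens the synthesis of raffinose-type sugars, rose from 0.183 ± 0.257 to 485 ± 482 FPKM (8.26 ± 0.51, adjusted p = 2.97e-07). The largest decreases were in the proline-rich protein DC2.15 (Potri.018G025900), from 1418 ± 382 to 1.12 ± 1.70 FPKM (-9.63 ± 0.50, adjusted p = 1.07e-07), a pEARLI1-like lipid transfer protein (Potri.006G065500, -9.10 ± 0.37, adjusted p = 2.34e-08) and proline-rich protein 4 (Potri.009G129900, -9.03 ± 0.69, adjusted p = 1.39e-06). Near-identical copies, such as the seed maturation pair, may share reads.

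Genes of abscisic acid (ABA), the hormone of water stress, moved widely in WT leaves. The synthesis enzyme NCED1 (Potri.011G112400) rose from 3.65 ± 0.428 to 194 ± 76.1 FPKM (5.31 ± 0.31, adjusted p = 2.12e-07) and the breakdown enzyme ABA 8'-hydroxylase 1 (Potri.004G235400) from 3.62 ± 0.966 to 208 ± 37.1 FPKM (5.51 ± 0.22, adjusted p = 2.31e-08), while zeaxanthin epoxidase (Potri.005G138400) fell (-3.57 ± 0.25, adjusted p = 8.47e-07). Of the 16 tested genes of ABA synthesis and breakdown 5 rose and 5 fell, and the list did not pass its test (camera adjusted p = 0.781). In ABA signalling 23 of 39 genes rose, including protein phosphatase 2C 3 (Potri.009G037300, 5.24 ± 0.26, adjusted p = 7.32e-08), and 5 fell, including the receptor PYL2 (Potri.006G230600, -3.0 ± 0.25, adjusted p = 2.39e-06). Adjusted over the list alone, the counts of both ABA lists were the same. In the dehydration response list, 25 of 40 genes rose and 6 fell (adjusted over the list alone, 26 and 6), and the homeobox gene ATHB-7 (Potri.014G103000) rose from 9.37 ± 6.36 to 725 ± 197 FPKM (6.37 ± 0.49, adjusted p = 1.38e-06). ABA signalling (camera adjusted p = 0.0136) and dehydration response (camera adjusted p = 0.00126) were higher as lists. Each had adjusted p = 0.954 with an estimated correlation.

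Photosynthesis and growth genes fell together. Of the 53 genes of the photosystems and their antennae 51 fell and 0 rose, with a median change of -3.09. The antenna gene described as chlorophyll a-b binding protein 21 (Potri.011G079500) fell from 2509 ± 446 to 18.6 ± 4.38 FPKM (-7.01 ± 0.39, adjusted p = 1.62e-07). In the Calvin cycle 14 of 16 genes fell and 1 rose, and a Rubisco small chain (Potri.004G100000) fell from 7565 ± 1112 to 243 ± 210.2 FPKM (-5.30 ± 0.72, adjusted p = 9.42e-05). Among cell division genes 26 of 38 fell and 4 rose. Adjusted over the list alone, the counts of these 3 lists were the same. The tests gave camera adjusted p = 1.14e-20 for photosystems, 1.50e-05 for the Calvin cycle and 9.80e-06 for cell division. For each of the 3, adjusted p = 0.954 with an estimated correlation.

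Vascular, wall and water transport genes fell more often than they rose in WT drought. In the xylem secondary wall list 33 of 53 genes fell and 9 rose (33 and 10 adjusted over the list alone), among them the lignin-polymerising enzymes laccase-12 (Potri.008G073800, -4.29 ± 0.55, adjusted p = 6.57e-05) and, upward, laccase-15 (Potri.011G071100, 4.86 ± 0.45, adjusted p = 5.51e-06). In the phloem list 14 of 27 fell and 3 rose (14 and 4 adjusted over the list alone), as with a SIEVE ELEMENT OCCLUSION B gene (Potri.012G090400, -4.42 ± 0.45, adjusted p = 1.13e-05). Of the aquaporins, water channels, 21 of 42 fell and 10 rose (21 and 11 adjusted over the list alone), with PIP1-2 (Potri.009G128500) at -6.72 ± 0.43 (adjusted p = 4.16e-07). Among wall expansion genes 25 of 55 fell and 15 rose (26 and 17 adjusted over the list alone). Expansin-A8 (Potri.013G154700), a wall-loosening protein, fell from 586 ± 135 to 1.3 ± 0.678 FPKM (-8.01 ± 0.40, adjusted p = 7.73e-08) while expansin-B2 (Potri.014G066300) rose (6.89 ± 0.41, adjusted p = 2.37e-07). Of the antioxidant enzymes 11 of 23 fell and 3 rose, the same when adjusted over the list alone, with catalase-2 (Potri.005G100400) at -3.09 ± 0.47 (adjusted p = 2.11e-04). As lists all 5 were lower, with camera adjusted p = 4.90e-04 (xylem), 0.00176 (phloem), 0.00763 (aquaporins), 0.0122 (wall expansion) and 0.0433 (antioxidant). For each of the 5, adjusted p = 0.954 with an estimated correlation. The xylem list did not pass with directional fry (adjusted p = 0.137). The wall expansion call ended without WT drought replicate 6 (0.0702) and with median-of-ratios scaling (0.0933). The antioxidant call ended without WT watered replicate 1 (0.0527), WT drought replicate 4 (0.0598) or 6 (0.0606), and OE watered replicate 2 (0.0527) or 3 (0.0535). Over the alternatives these lists reached 0.954, the value with an estimated correlation.

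Stomatal genes in WT drought went both ways. EPFL9 (Potri.002G249901), the peptide stomagen that promotes stomata, fell from 24.4 ± 5.08 to 0.0929 ± 0.161 FPKM (-4.53 ± 0.31, adjusted p = 6.46e-07), and a receptor kinase of the ERL type (Potri.004G001000) fell as well (-2.56 ± 0.32, adjusted p = 5.01e-05). Of the 35 stomatal lineage genes 8 rose and 11 fell. Of the 4 guard cell genes 2 rose and 2 fell, with the potassium channels KAT3 (Potri.018G035500, 1.62 ± 0.25, adjusted p = 2.59e-04) and KAT1 (Potri.004G132200, -1.85 ± 0.23, adjusted p = 5.18e-05) moving apart. Other lists with calls in both directions were the circadian clock (12 rose and 6 fell of 27, with the morning gene LHY, Potri.014G106800, at -4.23 ± 0.93, adjusted p = 0.00254), heat shock and chaperones (23 rose and 11 fell of 61) and flowering and age (9 rose and 7 fell of 30). Adjusted over the list alone, the counts of these 5 lists were the same. Among wax and cutin genes 9 rose and 12 fell of 35, also when adjusted over the list alone. Among senescence and chlorophyll breakdown genes 11 rose and 9 fell of 28 (11 and 10 adjusted over the list alone). None of these 7 lists passed its test in WT, with camera adjusted p from 0.187 (wax and cutin) to 0.890 (guard cell). Jasmonate genes also went both ways in WT drought (12 rose and 7 fell of 34, the same adjusted over the list alone, camera adjusted p = 0.687), as did phenylpropanoid and flavonoid genes (8 and 8 of 41, 6 and 8 adjusted over the list alone, camera adjusted p = 0.490). The meristem list matched 1 gene, which was too weakly expressed to test.

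Over all genes 8614 rose and 5501 fell in WT drought, 55.6% of the 25373 tested. Of the tested genes 62.9% had no overlap between the groups, against 10% by chance. At a log2 fold change of at least 1 the counts were 3965 and 3993. The split depended on the scaling: 61.0% of the changed genes were higher with FPKM as deposited, with a median change of all genes of 0.245, and 45.1% with median-of-ratios scaling (5681 higher, 6929 lower), with a median of 0.005.

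The second comparison asks the same of OE leaves. Galactinol synthase 1 (Potri.008G101000) rose from 0.314 ± 0.478 to 2413 ± 299 FPKM (10.89 ± 0.51, adjusted p = 2.92e-08). Next by size were ACC oxidase 1 (Potri.002G224100), which makes ethylene, from 1.46 ± 0.732 to 1761 ± 432 FPKM (9.51 ± 0.52, adjusted p = 7.58e-08), a berberine bridge enzyme-like protein (Potri.006G128900, 8.97 ± 0.62, adjusted p = 3.58e-07), a basic 7S globulin (Potri.002G054900, 8.24 ± 0.56, adjusted p = 2.97e-07) and ACC synthase 1 (Potri.002G163700), which precedes the oxidase in ethylene synthesis (8.07 ± 0.40, adjusted p = 4.28e-08). The largest decreases were in proline-rich protein 4 (Potri.009G129900, -9.12 ± 0.69, adjusted p = 6.39e-07) and chloroplast carbonic anhydrase (Potri.001G348900), from 2009 ± 514 to 2.85 ± 0.147 FPKM (-8.99 ± 0.23, adjusted p = 7.69e-10). NCED1 (Potri.011G112400) and ABA 8'-hydroxylase 1 (Potri.004G235400) rose as in WT (4.09 ± 0.31, adjusted p = 6.60e-07, and 4.13 ± 0.22, adjusted p = 6.65e-08). EPFL9 (Potri.002G249901) fell from 17.8 ± 8.03 to 0.0303 ± 0.0525 FPKM (-4.08 ± 0.31, adjusted p = 6.66e-07).

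Photosynthesis lists were lower in OE drought too. Of the 53 photosystem and antenna genes 50 fell and 0 rose, with a median of -5.03, and chlorophyll a-b binding protein 21 (Potri.011G079500) fell from 1829 ± 554 to 4.70 ± 3.35 FPKM (-8.45 ± 0.39, adjusted p = 2.86e-08). In the Calvin cycle 14 of 16 fell and 1 rose, in cell division 27 of 38 fell and 2 rose, in phloem 16 of 27 fell and 1 rose, and of the antioxidant enzymes 17 of 23 fell and 1 rose. Adjusted over the list alone, the counts of these 5 lists were the same. The dehydration response list had 25 of 40 genes higher and 8 lower (adjusted over the list alone, 26 and 8). The camera adjusted p was 5.47e-17 (photosystems), 4.92e-04 (Calvin cycle), 6.13e-04 (cell division), 0.00451 (phloem), 0.00232 (antioxidant) and, upward, 0.00246 (dehydration). For each of the 6, adjusted p = 0.954 with an estimated correlation. The dehydration list's p was 0.155 with the list patterns before exclusions were added.

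Jasmonate and phenylpropanoid genes of OE leaves included large increases, without a list call. Of 34 jasmonate genes 15 rose and 12 fell (adjusted over the list alone, 16 and 12; camera adjusted p = 0.134). The repressor genes TIFY 10b (Potri.003G068900, 6.80 ± 0.76, adjusted p = 1.17e-05) and TIFY 9 (Potri.003G165000, 6.50 ± 0.43, adjusted p = 2.47e-07) were among them. Of 41 phenylpropanoid and flavonoid genes 19 rose and 9 fell, the same when adjusted over the list alone (camera adjusted p = 0.0743), with chalcone synthase 1 (Potri.001G051600), the entry to flavonoid synthesis, at 4.00 ± 0.37 (adjusted p = 2.52e-06). In the stomatal lineage 14 rose and 16 fell of 35 (adjusted over the list alone, 14 and 17). The largest increase there was in a kinase described as YODA (Potri.005G139300, 5.37 ± 0.45, adjusted p = 1.23e-06), which lies in a cluster of near-identical copies that may share reads. In all, 7051 genes rose and 8890 fell in OE drought, 62.8% of those tested, and 70.0% had no overlap between the groups (10% by chance). At a log2 fold change of at least 1 these were 4324 and 6135.

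The drought responses of the genotypes overlapped. In WT and OE leaves 5460 genes rose in both and 5013 fell in both, against 2394 and 1927 for independent lists of these sizes. Another 225 genes changed in opposite directions. All 225 also passed the test of the difference, which adds no support, since opposite calls in both genotypes nearly fix that outcome. The responses, which share no libraries, correlated at r = 0.852 across genes, and genes are not independent replicates.

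**Figure D3:**
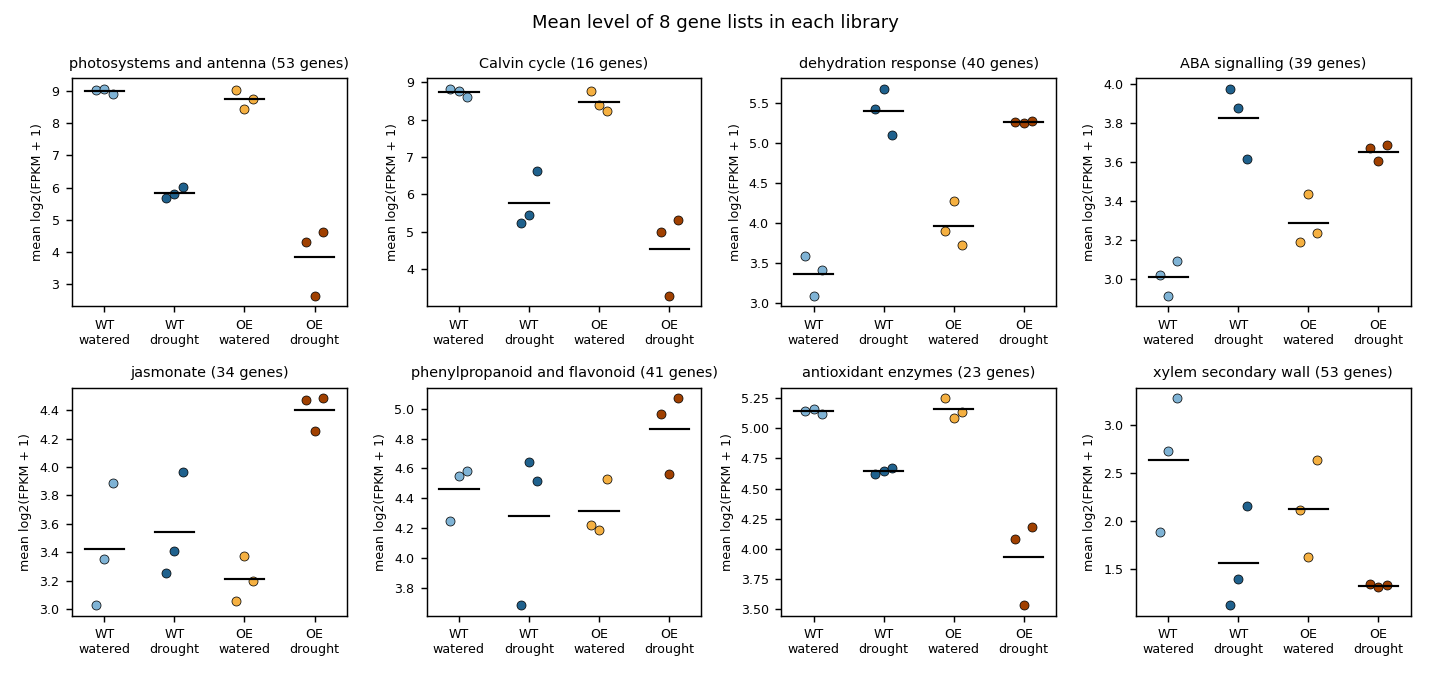
Mean log2(FPKM + 1) of 8 gene lists (vertical axis) in the 4 groups (horizontal axis), with bars for group means and a point for each of the 3 libraries. Photosystem genes fall in drought in both genotypes (median change -3.09 in WT and -5.03 in OE), and jasmonate genes are higher in OE than WT drought leaves (median difference 0.37).

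The third comparison sets OE against WT leaves when watered, and few genes differed. ATHB-7 (Potri.014G103000, chromosome 14, 8085842 to 8087890, minus strand), a homeobox gene known to respond to ABA and water deficit, stood at 9.37 ± 6.36 FPKM in WT and 1435 ± 363 FPKM in OE leaves (7.37 ± 0.49, adjusted p = 1.12e-04). The sucrose transporter SUC2 (Potri.013G115200) was higher in OE, at 3.12 ± 0.608 against 0.223 ± 0.12 FPKM (1.75 ± 0.16, adjusted p = 0.00127). A gene described as RADIALIS (Potri.004G155400) was lower, at 0.191 ± 0.331 against 6.42 ± 2.54 FPKM (-2.61 ± 0.26, adjusted p = 0.00182), as was the metalloendoproteinase 2-MMP (Potri.019G073800), at 6.22 ± 2.08 against 39.1 ± 10.9 FPKM (-2.48 ± 0.27, adjusted p = 0.00363). ABA 8'-hydroxylase 1 (Potri.004G235400) was higher, at 11.5 ± 2.18 against 3.62 ± 0.966 FPKM (1.45 ± 0.22, adjusted p = 0.0312). In total 25 genes were higher and 10 lower, and 2277 had an unadjusted p under 0.05. Another split of the 6 watered samples, which mixes the genotypes, called 34 genes against these 35, so the count alone does not set the genotypes apart. Of the tested genes 17.5% had no overlap between the groups, where chance gives 10%.

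These calls depended on the whole fit. With only the watered libraries fitted 0 genes were higher and 0 lower with limma, and with voom on recovered fragments in the whole design 12 were higher and 5 lower. The p was 0.0846 for ATHB-7 (range 1.54e-05 to 0.0846), 0.107 for SUC2 (range 2.53e-04 to 0.107), 0.109 for RADIALIS (range 8.02e-04 to 0.109) and 0.107 for 2-MMP (range 0.00326 to 0.215), and these 4 genes kept their calls without each library. The call of ABA 8'-hydroxylase 1 ended without WT watered replicates 1, 2 and 3 (0.0945, 0.202 and 0.0605), WT drought replicate 5 (0.0511), OE watered replicates 1 and 2 (0.134 and 0.142) and OE drought replicates 4 and 6 (0.0684 and 0.0526), and with voom, in a range of 0.0137 to 0.202. The numbers of higher and lower genes were 8 and 3 without WT watered replicate 1, 4 and 3 without WT watered 2, 21 and 5 without WT watered 3, and 65 and 18 without WT drought 6. They were 8 and 4 without OE watered 1, 11 and 8 without OE watered 2, 58 and 179 without OE watered 3, 10 and 6 without OE drought 4 and 13 and 6 without OE drought 6. With median-of-ratios scaling they were 20 and 14, or 58.8% higher against 71.4%.

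By list, watered OE leaves differed from WT in 7 lists, of which few members passed singly. The mean level of the xylem list overlapped between the genotypes by library, at 1.89 to 3.28 in WT and 1.63 to 2.64 in OE on the log2(FPKM + 1) scale. The dehydration response list had 2 of 40 genes higher and 0 lower (adjusted over the list alone, 5 and 0; median 0.23), and ABA signalling 0 and 0 of 39 (adjusted over the list alone, 3 and 0; median 0.30). Lower as lists were xylem secondary wall (median -0.47), photosystems and antenna (median -0.27), wall expansion (median -0.10) and wax and cutin (median -0.13), and the circadian clock was higher (median 0.16). Adjusted over all genes or over the list alone, 0 genes passed in the xylem, photosystem and clock lists, against 5, 1 and 6 at an unadjusted p under 0.05 and 0 with voom. In wall expansion and wax and cutin, 0 passed over all genes and 3 and 1 were lower when adjusted over the list alone, against 12 and 6 genes at an unadjusted p under 0.05 and 0 with voom. With directional fry only the dehydration list passed (adjusted p = 0.0491), and the others ran from 0.0845 (ABA signalling) to 0.724 (photosystems). The dehydration list holds ATHB-7 and was not tested without that gene. The camera adjusted p was 3.14e-07 (xylem), 1.96e-04 (photosystems), 3.18e-04 (ABA signalling), 9.39e-04 (dehydration), 0.00149 (wall expansion), 0.00208 (wax and cutin) and 0.0317 (clock). For each of the 7, adjusted p = 0.954 with an estimated correlation. Without OE watered replicate 2, the library nearest to the drought groups on the first principal component, it was 0.113 for photosystems (0.00757 without this library, WT drought replicate 6 and OE drought replicate 5), 0.129 for wall expansion, 0.0527 for wax and cutin and 0.194 for the clock. The wax and cutin call also ended without OE watered replicate 1 (0.0802), and the clock call without WT watered replicates 2 (0.0633) and 3 (0.211). With the list patterns before exclusions were added, p was 0.180 for dehydration and 0.532 for the clock.

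The size of 5 of these watered list shifts, as the mean log2 difference over the list, also moved with single libraries. The xylem mean of -0.51 was -0.88 and -0.19 without WT watered replicates 1 and 3 and -0.26 without OE watered replicate 2. Without OE watered replicates 1 and 2 the photosystem mean of -0.26 was -0.41 and -0.11. Without OE watered replicates 1, 2 and 3 the wall expansion mean of -0.17 was -0.09, -0.06 and -0.35, and the wax and cutin mean of -0.18 was -0.06, -0.11 and -0.36. The clock mean of 0.23 was 0.14 without OE watered replicate 2.

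The fourth comparison sets OE against WT leaves in drought. The exocyst gene EXO70A1 (Potri.001G234600), of the secretion machinery, stood at 3.43 ± 2.81 FPKM in WT and 244 ± 56.1 FPKM in OE leaves (5.95 ± 0.45, adjusted p = 1.91e-05). The calcium-binding protein CML37 (Potri.002G001400) stood at 1.04 ± 0.289 in WT against 50.5 ± 13.4 FPKM in OE (4.64 ± 0.26, adjusted p = 2.73e-06). Thaumatin-like protein 1 (Potri.005G112700), of a pathogen-related family, was higher by 4.58 ± 0.20 (adjusted p = 1.29e-06), as was a plasma membrane calcium ATPase (Potri.008G159100, 4.53 ± 0.25, adjusted p = 2.73e-06). The gene YLS3 (Potri.003G217000) was lower in OE, at 2.22 ± 0.373 against 51.2 ± 14.3 FPKM (-3.98 ± 0.23, adjusted p = 3.51e-06), as was a GDSL esterase (Potri.001G191400, -3.88 ± 0.44, adjusted p = 2.11e-04).

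Photosystem genes were lower still in OE than in WT drought leaves. Of 53 photosystem and antenna genes 49 were lower and 1 higher, the same when adjusted over the list alone, with a median of -2.07. The psaK subunit of photosystem I (Potri.006G254200) differed by -3.14 ± 0.55 (adjusted p = 0.00248). Of the antioxidant enzymes 12 of 23 were lower and 0 higher, the same when adjusted over the list alone, such as a Cu-Zn superoxide dismutase (Potri.019G035800, -1.34 ± 0.23, adjusted p = 0.00226). Both lists were lower (camera adjusted p = 5.87e-12 and 0.00232). For both, adjusted p = 0.954 with an estimated correlation. OE drought replicate 5 stood below the other OE drought libraries in the mean log2 level of both lists, at 2.64 against 4.30 and 4.63 (photosystems) and 3.53 against 4.09 and 4.18 (antioxidant), and without it the mean differences went from -1.98 to -1.37 and from -0.71 to -0.51.

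Jasmonate and flavonoid genes were higher in OE drought leaves. Of 34 jasmonate genes 13 were higher and 4 lower (adjusted over the list alone, 13 and 5), with allene oxide synthase 3 (Potri.009G109700, 2.73 ± 0.28, adjusted p = 1.44e-04) and OPR3 (Potri.018G065600, 2.63 ± 0.59, adjusted p = 0.00788), both enzymes of jasmonate synthesis, and TIFY 9 (Potri.003G165000, 2.71 ± 0.43, adjusted p = 0.00149), a repressor of the response. Of 41 phenylpropanoid and flavonoid genes 13 were higher and 4 lower (adjusted over the list alone, 14 and 4), with the near-identical chalcone synthase 1 genes Potri.001G051600 at 2.40 ± 0.37 (adjusted p = 0.00121) and Potri.001G051500 at 2.12 ± 0.34 (adjusted p = 0.00161). The camera adjusted p was 1.50e-04 for jasmonate and 1.50e-05 for phenylpropanoids. With directional fry neither list passed (adjusted p = 0.0845 and 0.134). For both, adjusted p = 0.954 with an estimated correlation. The mean log2 levels of the phenylpropanoid list overlapped by library, at 3.68, 4.64 and 4.51 in WT and 4.96, 4.56 and 5.07 in OE drought, and without WT drought replicate 4 the mean difference was 0.29 in place of 0.59.

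Guard cell, water and ABA genes differed one by one in drought. The guard cell channel KAT1 (Potri.004G132200) stood at 1.05 ± 0.540 FPKM in WT and 6.53 ± 1.5 FPKM in OE leaves (1.89 ± 0.23, adjusted p = 3.30e-04), and the aquaporin PIP2-5 (Potri.010G222700) at 402 ± 78.3 and 1932 ± 111 FPKM (2.28 ± 0.23, adjusted p = 1.17e-04). The kinase SRK2E (Potri.009G106900), known to pass the ABA signal in guard cells, was lower in OE (-1.42 ± 0.19, adjusted p = 4.85e-04), as were a second ATHB-7 gene (Potri.001G083700, -2.38 ± 0.36, adjusted p = 0.00121) and RD22 (Potri.006G243700, -2.38 ± 0.41, adjusted p = 0.00232). Aquaporins had 7 genes higher and 7 lower of 42 (7 and 9 adjusted over the list alone, camera adjusted p = 0.432) and the dehydration response 6 and 8 of 40 (the same adjusted over the list alone, camera adjusted p = 0.556), and neither list passed. Other lists that did not pass included ABA signalling (3 higher and 5 lower of 39, 3 and 4 adjusted over the list alone, camera adjusted p = 0.907), guard cell (2 and 0 of 4, the same adjusted over the list alone, camera adjusted p = 0.282) and epidermis and trichome (0 and 3 of 5, 1 and 3 adjusted over the list alone, camera adjusted p = 0.758). The stomatal lineage list had 7 higher and 5 lower of 35, the same adjusted over the list alone. It did not pass (camera adjusted p = 0.0589), and its median of -0.04 differed in sign from its mean of 0.18 and its test, which pointed up. Over the 110 list tests 31 had a median, mean and test that differed in sign, and 0 of the 31 passed camera's test.

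In total 2341 genes were higher and 5176 lower in OE than WT drought leaves, 29.6% of those tested, and 44.9% had no overlap between the groups (10% by chance). Without WT drought replicate 4 the lower genes numbered 2562, and without OE drought replicate 5 they numbered 2706. The split turned with the scaling: 31.1% of the changed genes were higher with FPKM as deposited and 60.1% with median-of-ratios scaling (3865 and 2561), where the median of all genes moved from -0.241 to -0.03. With only the drought groups fitted and FPKM as deposited, 45.5% were higher (1434 and 1717). Across the watered and drought comparisons, which share no libraries, 1 gene was higher and 1 lower in OE in both (2.31 and 2.04 for independent lists) and 8 changed in opposite directions, with r = -0.04 across genes.

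The interaction asks which genes answered drought differently in the genotypes, as the OE response minus the WT response. EXO70A1 (Potri.001G234600) rose in OE drought leaves to 244 ± 56.1 FPKM, from 0.672 ± 0.330 FPKM, while WT leaves held 1.83 ± 1.79 and 3.43 ± 2.81 FPKM (difference 6.55 ± 0.64, adjusted p = 4.34e-04). Larger responses in OE were also found for thaumatin-like protein 1 (Potri.005G112700, 5.25 ± 0.29, adjusted p = 1.46e-05), the stress-induced zinc finger gene ZAT11 (Potri.001G235800, 5.08 ± 0.62, adjusted p = 0.00129), CML37 (Potri.002G001400, 4.55 ± 0.37, adjusted p = 1.35e-04) and YLS9 (Potri.006G204300, 4.49 ± 0.46, adjusted p = 5.55e-04). ATHB-7 (Potri.014G103000) gave the largest negative difference (-6.46 ± 0.69, adjusted p = 6.48e-04), as it rose in WT but stood at 1435 ± 363 FPKM in watered and 1332 ± 207 FPKM in drought OE leaves. A dnaJ 11 chaperone (Potri.004G172300, -4.72 ± 0.72, adjusted p = 0.00350), YLS3 (Potri.003G217000, -4.55 ± 0.33, adjusted p = 7.22e-05) and abscisic stress-ripening protein 3 (Potri.005G193600, -4.32 ± 0.42, adjusted p = 4.31e-04) were also negative, and the latter went from 358 ± 85.5 to 12.1 ± 0.461 FPKM in OE.

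By list, jasmonate and flavonoid responses were larger in OE and photosystem responses more negative. Of 34 jasmonate genes 12 had a positive and 2 a negative difference (adjusted over the list alone, 13 and 3), such as OPR3 (Potri.018G065600, 3.70 ± 0.83, adjusted p = 0.0168) and TIFY 5A (Potri.011G083900, 3.21 ± 0.60, adjusted p = 0.00852). Of 41 phenylpropanoid and flavonoid genes these were 10 and 2 (adjusted over the list alone, 14 and 3), of 53 photosystem genes 0 and 16 (adjusted over the list alone, 1 and 41), of 23 antioxidant genes 0 and 7 (adjusted over the list alone, 0 and 10) and of 53 xylem genes 1 and 1, the same adjusted over the list alone. The antenna gene CP26 (Potri.019G063100) differed by -2.59 ± 0.49 (adjusted p = 0.00879) and ascorbate peroxidase 2 (Potri.006G132200) by -1.47 ± 0.27 (adjusted p = 0.00687). The camera adjusted p was 1.59e-05 (jasmonate) and 7.82e-06 (phenylpropanoids) and 0.00114 (xylem), all positive, and 8.23e-07 (photosystems) and 0.0152 (antioxidant), both negative. For each of the 5, adjusted p = 0.954 with an estimated correlation. The antioxidant call ended without OE watered replicate 1 (0.0532), and the xylem call with median-of-ratios scaling (0.0933). With directional fry the adjusted p was 0.125 (jasmonate), 0.206 (phenylpropanoids), 0.0759 (photosystems) and 0.737 (xylem), and only the antioxidant list passed (0.0193).

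Single libraries moved the size of some of these list differences, taken as the mean log2 difference over the list. Without WT drought replicate 4 the phenylpropanoid mean was 0.44 in place of 0.74, and without OE drought replicate 5 the photosystem mean was -1.11 in place of -1.72. The xylem mean of 0.28 was -0.04 without WT watered replicate 3, 0.65 without WT watered replicate 1, 0.06 and 0.58 without WT drought replicates 4 and 6, and 0.03 and 0.53 without OE watered replicates 2 and 3. Camera tests the xylem list against the other genes, whose median was -0.28, and not against 0.

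Single genes of water and guard cell biology also differed in their response, including KAT1 (Potri.004G132200, 2.00 ± 0.33, adjusted p = 0.00469), PIP2-5 (Potri.010G222700, 2.54 ± 0.32, adjusted p = 0.00166) and SRK2E (Potri.009G106900, -1.89 ± 0.26, adjusted p = 0.00232). Their lists went both ways and did not pass: aquaporins had 6 positive and 4 negative differences of 42 (7 and 8 adjusted over the list alone, camera adjusted p = 0.352), guard cell genes 1 and 1 of 4 (2 and 2 adjusted over the list alone, camera adjusted p = 0.582) and ABA signalling 1 and 7 of 39 (2 and 8 adjusted over the list alone, camera adjusted p = 0.181). KAT1 fell in WT drought from 6.22 ± 0.702 to 1.05 ± 0.540 FPKM and stood at 5.73 ± 0.891 and 6.53 ± 1.5 FPKM in watered and drought OE leaves. In the stomatal lineage 5 genes had a positive and 1 a negative difference of 35, the same adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0643). The YODA-type kinase Potri.005G139300 led them (4.21 ± 0.63, adjusted p = 0.00320).

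Over all genes 1163 differences were positive and 2659 negative, 15.1% of those tested. With median-of-ratios scaling 2036 were positive and 1052 negative, or 65.9% positive against 30.4%, and the median of all genes moved from -0.278 to 0.038. The positive counts were 659 without WT watered replicate 2, 706 without WT watered 3, 733 without WT drought 4, 1934 without WT drought 6, 662 without OE watered 1 and 740 without OE drought 4. The negative counts were 1280, 819 and 1525 without WT watered 1, 2 and 3, 1232, 1517 and 4794 without WT drought 4, 5 and 6, 1416 and 1596 without OE watered 1 and 2, and 1532 and 1581 without OE drought 4 and 5.

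**Figure D4:**
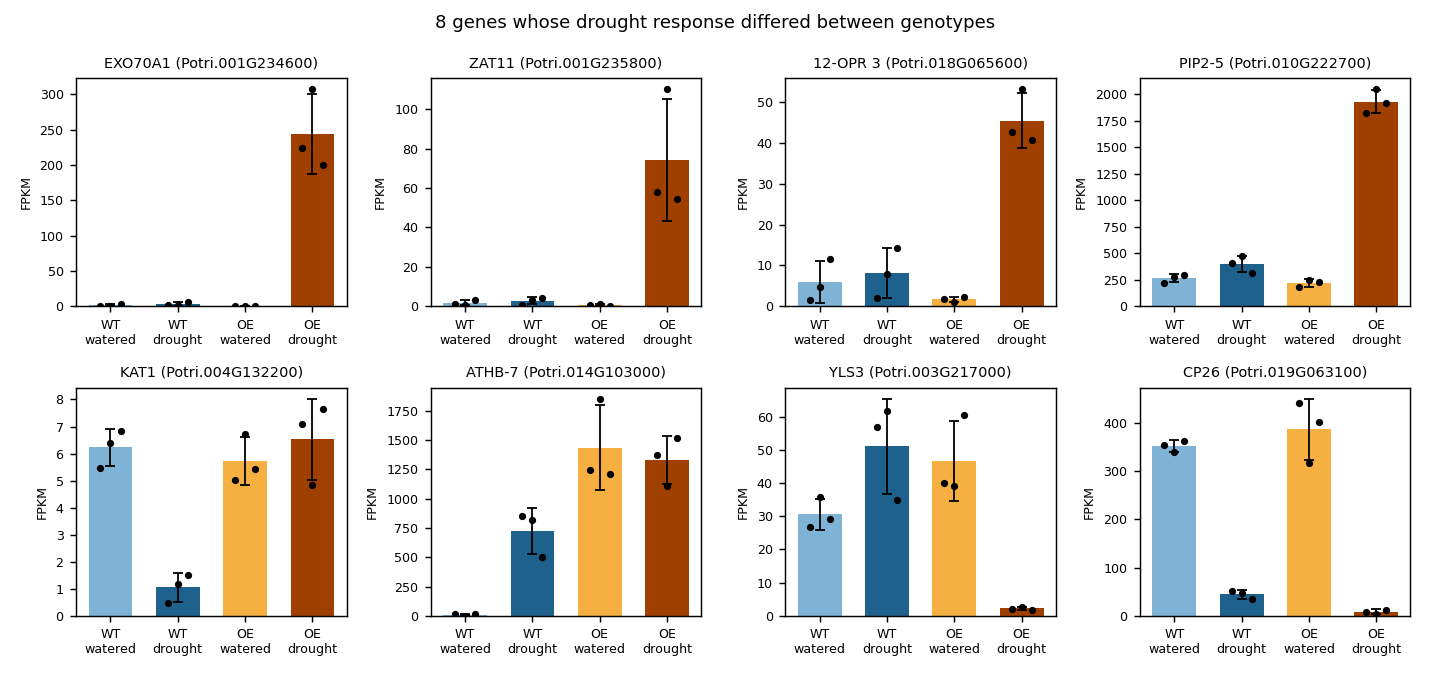
FPKM (vertical axis) of 8 genes whose drought response differs between the genotypes, in the 4 groups (horizontal axis), with bars for group means, error bars for the SD and points for the 3 libraries. EXO70A1 reaches 244 FPKM in OE drought leaves against 3.43 FPKM in WT, and ATHB-7 stands at 1435 FPKM in watered OE leaves against 9.37 FPKM in WT.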

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

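All tests of explanations given in this part, including the counts over other splits of the samples, were chosen or worded only after the results were seen; the interaction itself was planned.

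The drought response differed between OE and WT leaves by the test of the difference itself, with 1163 positive and 2659 negative genes, 3822 in all. These counts were 659 and 819 without WT watered replicate 2 and 1934 and 4794 without WT drought replicate 6, the lowest and highest without any library, and 2036 and 1052 with median-of-ratios scaling.

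Over 100 splits of all 12 samples into 4 groups of 3, 5 gave a count as large, the real one included, so chance cannot be excluded by this count. The highest other split gave 16100 genes, several times the real count, which points to the structure set by watering: the 4 other large splits put at least 5 of the 6 drought samples on one side. With the genotype labels shuffled only within watered and within drought samples, 1 of 100 splits, the real one, was as large, and the highest other gave 2612 genes. That argues against chance for the labels over both waterings together. This count mostly reflects the genotype difference in drought, since 11 of the other splits keep the drought samples in their genotypes, and those that mix them gave at most 2 genes. The splits that keep them, none as large, are too few for a share under 0.05, so the interaction itself was not settled by splits. The contrasts of 3 against 3 samples have 10 splits each, too few for a share under 0.05. The real counts there were 14115 (WT drought), 15941 (OE drought), 35 (OE against WT, watered) and 7517 (OE against WT, drought). The highest of the other splits gave 0, 0, 34 and 6, with 1 split of 10 as large in each, the real one. In watered leaves a split that mixes the genotypes thus called nearly as many genes as the real one.

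The differences that passed included these lists, by camera adjusted p: photosystems and antenna 8.23e-07, phenylpropanoid and flavonoid 7.82e-06, jasmonate 1.59e-05, xylem secondary wall 0.00114 and antioxidant enzymes 0.0152. Each had adjusted p = 0.954 with an estimated correlation. With directional fry only the antioxidant enzymes passed (adjusted p = 0.0193). Among named genes the OE response exceeded the WT response by a log2 of 6.55 ± 0.64 (EXO70A1, Potri.001G234600), 5.25 ± 0.29 (thaumatin-like protein 1, Potri.005G112700), 5.08 ± 0.62 (ZAT11, Potri.001G235800), 4.55 ± 0.37 (CML37, Potri.002G001400) and 4.49 ± 0.46 (YLS9, Potri.006G204300). The same held for the YODA-type kinase Potri.005G139300 (4.21 ± 0.63), OPR3 (Potri.018G065600, 3.70 ± 0.83), TIFY 5A (Potri.011G083900, 3.21 ± 0.60) and the chalcone synthase 1 genes Potri.001G051600 (2.67 ± 0.52) and Potri.001G051500 (2.67 ± 0.48). It also held for PIP2-5 (Potri.010G222700, 2.54 ± 0.32), KAT1 (Potri.004G132200, 2.00 ± 0.33), the xylan synthesis gene IRX14H (Potri.005G141500, 1.14 ± 0.25) and the AP2 gene Potri.005G140700 (1.11 ± 0.24). Negative differences were found for ATHB-7 (Potri.014G103000, -6.46 ± 0.69), dnaJ 11 (Potri.004G172300, -4.72 ± 0.72), YLS3 (Potri.003G217000, -4.55 ± 0.33), abscisic stress-ripening protein 3 (Potri.005G193600, -4.32 ± 0.42), CP26 (Potri.019G063100, -2.59 ± 0.49), SRK2E (Potri.009G106900, -1.89 ± 0.26), ascorbate peroxidase 2 (Potri.006G132200, -1.47 ± 0.27) and ascorbate peroxidase 3 (Potri.009G134100, -1.36 ± 0.30). Their adjusted p ran from 1.46e-05 to 0.0168.

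OE and WT leaves differed in drought in the jasmonate, flavonoid and photosystem lists by camera, each with adjusted p = 0.954 with an estimated correlation. Of these lists only the photosystems passed with directional fry (adjusted p = 0.0130). Scaling, which moves all genes of a library alike, was argued against as the cause of all differences, since at least 31.14% of the genes past the threshold lay on the smaller side, higher or lower, in each of the 3 scalings, but for many lower genes it stays open, since 49.5% of the 5176 stayed lower with median-of-ratios scaling. A candidate explanation is that OE leaves were further along the same drought response, and this stays open. Of the 2202 genes past the threshold in WT drought and in the interaction, 49.8% had an interaction of the sign of the WT response. Simulations gave 0.9%, but they held no drought effect, so that the shared WT libraries alone pulled the signs apart. Where drought itself sets the sign of the WT response, 0.9% is no baseline, and the share decides nothing. The slope of the OE on the WT response was 1.04, the median interaction was -0.20 for genes higher and -0.25 for genes lower in WT drought (all genes -0.28), and 1620 interaction genes (42.4%) were not past the threshold in WT drought, which leaves it undecided. Handling at harvest stays open for the jasmonate genes, which are also known to answer wounding: the lowest OE drought library lay 0.291 log2 above the highest WT drought library, and the design ties any such handling to genotype, which as the biological explanation was not separated from it.

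More genes were lower than higher in OE than in WT drought leaves (5176 against 2341). A few abundant genes were argued against as the cause, since 35.16% of the changed genes were higher with scaling outside the 100 most abundant genes. Library size was argued against too, since the groups' mean fragments had a ratio of 1.009. The authors' normalization stays open: with median-of-ratios scaling 60.15% were higher, but that scaling centres the median by construction and so cannot say which scaling is right. A broad shift of the leaf transcriptome with genotype is the biological alternative, and it was not tested apart from the scaling.

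Watered OE leaves showed 7 list shifts by camera, each with adjusted p = 0.954 with an estimated correlation. Of these only the dehydration response, a list that was not tested without its member ATHB-7, passed with directional fry (adjusted p = 0.0491). Without OE watered replicate 2, alone or with the 2 other libraries apart from their groups, ABA signalling, dehydration and xylem kept camera adjusted p of at most 0.0124. For ABA signalling the tables argue against that library as the whole cause. The list's mean log2 level was 3.192 and 3.234 in OE watered replicates 1 and 3, above 3.095, the highest of WT watered. For dehydration response these means also lay higher, at 3.903 and 3.717 against at most 3.58. ATHB-7, high in each watered OE library, is in that list, so for its other genes the question stays open. For xylem secondary wall it stays open too, since the library means overlapped and the mean difference went from -0.51 to -0.26 without that library. For photosystems this stays open, at 0.113 without that library alone and 0.00757 without the 3 libraries. For wall expansion, wax and cutin and the circadian clock the shift may rest on that library, since the lowest of their adjusted p in both fits was 0.0527, but the wax and cutin call also ended without OE watered replicate 1 (0.0802) and the clock call without WT watered replicates 2 (0.0633) and 3 (0.211), so this stays open too. A mild water deficit of the watered OE plants and an effect of the genotype are both open, and the design holds no test that parts them. Nor can an effect of the microRNA itself be told from any other difference of the OE plants.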

How the results depend on the processing

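The values without the 3 libraries apart from their groups, with voom, with scaling outside the 100 most abundant genes, with the first list patterns, and the list values without each replicate come from alternatives chosen after seeing the data; the others were planned. No named gene turned direction while past the threshold, and no list did by camera's test against the other genes. The mean of the xylem list in the interaction did change sign without WT watered replicate 3, while its call passed. With median-of-ratios scaling the balance of all genes turned, to 60.15% higher from 31.14% in OE against WT drought and to 65.93% from 30.43% in the interaction. Of the named calls 97 of 102 in WT drought, 100 of 104 in OE drought, 64 of 99 in OE against WT drought, 54 of 88 in the interaction and 0 of 19 in watered leaves held in every setting, and all 19 of the last ended with only the watered groups fitted. The depth of 9682111 to 12131416 fragments limits the weak genes most, and with 3 libraries per group a simulated interaction of a fold of 1.5 was recovered for 0% of 69 changed genes (24374 genes in the step). The tests planned for raw counts were not run, since the values are FPKM, though voom was run on the recovered fragments.

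Counts moved by over 1.5 times as follows, higher then lower. In watered OE against WT leaves, 25 and 10 genes became 16 and 3 with a pseudocount of 0.1, 16 lower with no filter, 0 and 0 with only the groups compared, 12 and 5 with voom, and 53 and 17 without the 3 libraries. In WT drought 8614 higher genes became 5681 with median-of-ratios scaling and 3965 at a log2 fold change of at least 1, where the 7051 of OE drought became 4324. In OE against WT drought, 2341 and 5176 became 3865 and 2561 with median-of-ratios scaling, 1434 and 1717 with only the groups compared, and 1356 and 2078 at a log2 fold change of at least 1. In the interaction 1163 and 2659 became 2036 and 1052 with median-of-ratios scaling, 741 higher with voom, and 2315 and 4518 without the 3 libraries. The 2 genes shared by both OE comparisons became 1 with median-of-ratios scaling, 0 with only the groups compared, 8 without the 3 libraries and 4 with scaling outside the 100 most abundant genes. The 33 lists became 0 with an estimated correlation and 84 with fry in either direction. With directional fry 14 of the 33 calls ended, and 19 other lists passed. With only the groups compared fewer samples give the spread, and of the other moves the cause was not tested.

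Without each library in turn, the counts ranged as follows. WT drought gave 6644 to 8956 higher and 4797 to 5724 lower genes, OE drought 6051 to 7431 and 7704 to 9317, watered OE against WT 4 (without WT watered 2) to 65 (without WT drought 6) and 3 (without WT watered 1 or 2) to 179 (without OE watered 3), OE against WT drought 1633 to 2925 and 2562 (without WT drought 4) to 6269, and the interaction 659 to 1934 and 819 to 4794 (without WT watered 2 and WT drought 6). The shared drought response ranged from 9068 (without WT watered replicate 2) to 10609 genes, the shared OE effect from 0 (without WT watered replicate 1) to 28 (without OE watered replicate 3), and the lists from 31 to 38.

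The replicate numbers are shared by OE and WT at each watering but did not pair the samples: same-numbered samples correlated in their deviations at 0.015, -0.497 and -0.017 (watered) and -0.054, 0.218 and 0.134 (drought), and not every sample correlated best with its own number. With the replicate block the watered counts were 4 and 1, the interaction counts 753 and 1399, the shared OE effect 0, and OE against WT drought 2046 and 4540.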

Other observations

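The term tests, the choice of opposite genes, the neighbours of ATHB-7 and the test of the target family were chosen only after the results were seen.

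Among genes whose drought response was opposite in the 2 genotypes, 193 rose in WT and fell in OE leaves and 32 did the reverse. By log2 fold change, a class III heat shock protein (Potri.003G071100) rose by 1.60 in WT (limma adjusted p = 0.00182) and fell by 1.91 in OE (adjusted p = 3.74e-04). A wound-responsive family protein (Potri.013G147700) rose by 1.75 in WT (adjusted p = 0.00424) and fell by 1.55 in OE (adjusted p = 0.00693). In the reverse direction a calmodulin-like protein 3 (Potri.T124900), which binds calcium, fell by 1.89 in WT (adjusted p = 0.00466) and rose by 1.64 in OE (adjusted p = 0.00855). The hydrolase ILR1-like 4 (Potri.010G035900), of a family that acts on hormone conjugates, fell by 1.39 in WT (adjusted p = 0.0103) and rose by 1.38 in OE (adjusted p = 0.00888), and the ubiquitin ligase RHA1B (Potri.001G101000) fell by 0.93 (adjusted p = 0.00749) and rose by 1.56 (adjusted p = 1.74e-04). These genes were chosen after their values were seen. The interaction of the heat shock protein (-3.51 ± 0.47, adjusted p = 0.00207) passed in every alternative, and for the others the alternatives were not run.

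Functional terms, 2858 over a background of 20032 genes, gave a wider view. Fisher's exact test, which gave the p-values of terms, takes genes as independent. Genes of a term may move together, so these p-values may be far too small. In WT drought 41 genes of the small-subunit processome were among those that rose (Fisher's exact adjusted p = 1.55e-08), and 238 genes of the thylakoid membrane among those that fell (86.9 expected, adjusted p = 2.98e-57). Translation (229 genes, 169.2 expected, adjusted p = 4.12e-06) and the response to chitin (82 genes, 51.6 expected, adjusted p = 4.68e-05) were also enriched in the genes that rose in WT. Of the 8614 genes that rose there, 5681 stayed higher with median-of-ratios scaling, and terms were not tested under that scaling. In OE drought, terms enriched in the genes that rose included the response to chitin (92 genes, 41.9 expected, adjusted p = 1.42e-14) and to wounding (97 genes, 54.6 expected, adjusted p = 9.09e-08). Leaf senescence was another (72 genes, 40.4 expected, adjusted p = 9.02e-06). Auxin-activated signalling was enriched in the genes that fell (149 genes, 89.2 expected, adjusted p = 1.31e-11). The senescence and chlorophyll breakdown list did not go with the senescence term: 10 of its 28 genes rose and 15 fell in OE drought (camera adjusted p = 0.774). Between genotypes in drought, the genes higher in OE were enriched in the response to chitin (52 genes, adjusted p = 3.18e-15), wounding (54 genes, adjusted p = 2.54e-11) and ethylene signalling (50 genes, adjusted p = 1.32e-06). The genes lower in OE were enriched in translation (251 genes, 98.4 expected, adjusted p = 1.05e-51), the thylakoid membrane (187 genes, 84.5 expected, adjusted p = 1.96e-27) and the ribosome (122 genes, 49.4 expected, adjusted p = 1.19e-22). Which genes count as lower here depends on the scaling, since 2561 of the 5176 stayed lower with median-of-ratios scaling.

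ATHB-7 (Potri.014G103000) was high in each watered OE library, at 1242, 1854 and 1210 FPKM against 14.4, 2.21 and 11.5 FPKM in the watered WT libraries. Of the 10 genes on each side of it 17 were tested between watered genotypes, with log2 differences from -1.16 to 0.85, and none of these 17 passed the threshold with limma. A second ATHB-7 gene (Potri.001G083700) stood at 1.95 FPKM in watered WT and 4.65 FPKM in watered OE leaves.

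A hypothesis from the design is that the overexpressed microRNA lowers its target transcripts to a log2 fold change of -1 or less in watered leaves. For the 6 genes described as AP2 the values argued against a difference of that size between the libraries labelled OE and WT. All 6 had a 95% interval above -1, each taken singly, with a lowest bound of -0.69. The level of the microRNA was not analysed here, so an OE line without raised microRNA in these leaves would give the same result. Repression of translation, which these data do not measure, or repression smaller than these intervals stays possible.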
